A study of Arabidopsis thaliana and Antirrhinum majus with 10 samples.

How the data were processed

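The 10 samples of the series were used, each a 2-colour Agilent array, and all RNA was treated as from leaves of Antirrhinum majus. The labels conflict on this: the organism field gives Arabidopsis thaliana for the 6 samples on the Arabidopsis designs, while the growth protocol of all 10 names Antirrhinum plants. The 2 channels of an array held cin-756 and wild-type JI-98 RNA, or base and tip of wild-type leaves. The dye of each RNA was taken from the labels.

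Scanner files held intensity per spot, the mean pixel signal and a local background median for the green (Cy3) and red (Cy5) channel, as deposited. Per the file headers these were made with Agilent Feature Extraction, version 9.1.3.1 for the Arabidopsis designs and 9.5.1.1 for the Antirrhinum design. The same files held processed intensity, background-subtracted, detrended and dye-normalized with a linear and a LOWESS step per the file headers, and a log10 ratio of processed red over green per the file headers. The deposited series matrix held a log2 ratio per spot. Its direction was found by setting each column against the scanner ratios, with which all 10 columns correlated positively as cin over wild type or base over tip (r from 0.28 to 0.89), its column medians lay between -0.04 and 0.00, and its normalization method stays unknown. Per the labels' protocols, RNA was amplified and labelled by in vitro transcription.

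Scanner values were corrected with the normexp method of limma 3.58.1 in R 4.3.3 (offset 50) and normalized within each array by loess, with control spots given no weight and then left out, and outlier spots set to missing. Ratios were turned so that every array gave cin over wild type or base over tip. Spots of a probe were averaged. For each locus the kept probe of highest mean intensity was used; with several kept probes, their signs differed at 2 of 6 loci on the Arabidopsis design and at 185 of 595 on the Antirrhinum design, and none spread over more than 1 on the log2 scale. A probe was kept on the Arabidopsis 44k design if it was well above background in at least 1 channel on at least 1 array of every replicate (3141 probes, 3130 genes), and on the Antirrhinum design if so on both young arrays (15976 probes, 15372 features). Counts, lists and named genes of single arrays used features well above background in both channels. Their correlations with other arrays, and the comparison of young with mature leaves, needed this in only 1 channel. Every gene named from the replicated comparisons was above background in both groups, so no fold is given as a bound. Probes were named by the Arabidopsis locus in the files. With Antirrhinum RNA these names are labels of probes, and which member of a gene family a probe read was not tested. Of 25671 such loci, 25455 were in the reference table and 10211 had a symbol there. The Antirrhinum design held 13688 probes for Antirrhinum transcript assemblies (84.3% above background) and 25762 custom probes for Arabidopsis loci (13.7% above background). It also held 1490 catalogue probes for Arabidopsis loci (78.7%) and 2726 others (27.7%). CINCINNATA itself could not be assigned to a probe from the files.

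Arrays of the same replicate number on the 44k design were averaged, since the labels give them as dye swaps, and the 3 replicate means were tested against 0 with limma (lmFit, eBayes) and Benjamini-Hochberg adjustment at 0.05. The 2 young Antirrhinum arrays were tested the same way. The 22k array was described beside them, as were the mature and the base over tip arrays, which are single. Gene lists were fixed before the data were examined: 22 lists of Arabidopsis loci on cytokinin, auxin, cell cycle, histones, TCP factors, jasmonate, gibberellin, leaf development, cell wall, photosynthesis, epidermis, vascular tissue, stomata, stress and ribosome. The ribosome list was filled by fixed keywords in the probe descriptions and may hold some proteins of organelle ribosomes. Lists with at least 5 measured members were tested with camera (preset correlation 0.01), and with camera at an estimated correlation and fry beside it; the background was all measured loci. Camera compares a list with other genes. Fry tests whether a list's genes move one way, or in its mixed form either way, and makes no such comparison. With so few replicates, camera at an estimated correlation has little power. A call lost there does not show that correlated genes produced it. On single arrays a list's median was set against 10000 random lists of the same size matched on intensity, which describes those arrays alone. Correlations across loci were descriptive.

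Named genes followed a rule written before the data were examined: genes past the threshold, filled up to 5 per side by smallest p among genes of 1 sign in every replicate; CINCINNATA's class II TCP relatives, AHK4, IAA3, CYCD3 and type-A response regulators where measured; and for single arrays the 10 highest and 10 lowest annotated, unsaturated loci. The scripts were tested on simulated data with the fitted spread of each comparison. Of 100 genes changed by 1 on the log2 scale among 3130 genes in 3 replicates, 93% were called, and 97% of 100 changed by 2, with 15 false calls. Of 100 changed by 2 among 15372 features in 2 replicates 71% were called, and 0% of 100 changed by 1, with 6 false calls. A list of 10 genes shifted by 0.5 was detected in both. Each simulation changed 200 genes at once with independent errors. These shares therefore do not give the power where few genes change, since the adjusted threshold is then stricter.

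Slides followed the design only in part. Replicates 2 and 3 of the 44k design shared 1 slide and scan, the replicate 1 array was alone on another, and the 22k array was on its own. The 4 Antirrhinum arrays shared 1 slide and the young pair 1 scan. Alternatives were no background subtraction, median centring, Agilent's processed ratios, the series matrix values, other signal filters, the mean over probes, dye and block terms, the 22k array joined to replicate 1, and leaving out each replicate. Their effect is given in the closing section.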

Results

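Leaves of snapdragon (Antirrhinum majus) were compared between the wild-type stock JI-98 and the mutant cin-756, which carries a lesion in CINCINNATA, a class II TCP transcription factor gene needed for flat leaf growth. On each array cin RNA was hybridised against wild-type RNA in the other dye, except on 1 array that compared 2 wild-type tissues. Young leaves of 3 to 5 mm were measured on 6 Arabidopsis arrays, of which 5 were of a 44k design covering replicates 1 to 3 and 1 was of a 22k design. They were also measured on 2 arrays of a custom Antirrhinum design, with the dyes exchanged between replicates 1 and 2. Mature leaves of 20 mm were measured on 1 Antirrhinum array, and the proliferating base of a 5 mm wild-type leaf was set against the tip of a 20 mm wild-type leaf on another. Antirrhinum RNA gave a signal well above background in at least 1 channel for 7.81 to 13.3% of the probes on the Arabidopsis 44k arrays and for 7.83% on the 22k array. That share was 32.8 to 40.3% on the Antirrhinum arrays. All ratios below are log2 of cin over wild type, or of base over tip, and the number of arrays limits their precision.

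Young cin leaves on the Arabidopsis 44k design addressed which transcripts differ when the leaf starts to curve. No gene of 3130 passed the limma test at an adjusted p of 0.05, while 168 had an unadjusted p under 0.05, 100 of them higher and 68 lower in cin, against 156 expected by chance. The 5 increases of smallest p among genes of 1 sign in every replicate did not pass the threshold. AT3G07840, a putative polygalacturonase of pectin breakdown, was 0.66 ± 0.02 higher on the log2 scale (SD, n = 3, adjusted p = 0.236). Replicates 2 and 3 are means of dye-swapped arrays, so the SDs given here leave out the spread between single arrays. For AT3G07840 the 5 arrays ran from 0.27 to 1.05. The extensin-like gene AT4G08400 stood at 0.53 ± 0.11 and AT4G11430 at 0.57 ± 0.13 (both adjusted p = 0.349). AT3G20820 reached 0.89 ± 0.17 and the mitochondrial cytochrome b locus AT2G07727 reached 0.93 ± 0.21 (both adjusted p = 0.349).

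The 5 decreases chosen the same way were smaller, and none passed. CCoAOMT1, a methyltransferase of lignin precursor synthesis, stood at -0.41 ± 0.04 (SD, n = 3, adjusted p = 0.349). The ribosomal protein L30 gene AT1G36240 was at -0.39 ± 0.09 and the glycosyltransferase gene AT3G10630 at -0.30 ± 0.03 (both adjusted p = 0.444). The cytochrome b561 gene ACYB-2 was at -0.31 ± 0.05 and the glyoxalase gene AT1G67280 at -0.29 ± 0.05 (both adjusted p = 0.544). On single arrays ACYB-2 ran from -0.67 to 0.10, so its sign differed between arrays. In simulated data with the spread of these 3 replicates and 200 genes changed at once, 93% of genes changed by 1 on the log2 scale were called. That share does not carry over to a few changed genes. In the real data AT2G07727 at 0.93 did not pass.

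The auxin and cytokinin genes that the study's title concerns gave few measurable probes. The Aux/IAA repressor gene IAA3 was lower in all 3 replicates, at -0.58, -0.46 and -0.19. Its mean of -0.41 ± 0.20 did not pass (adjusted p = 0.750). The -0.58 of replicate 1 rests on a single array, and its dye-swap partner, of another design, gave 0.0003 for IAA3. The signal there was dim, with log2 levels of 6.72 in both channels. In replicate 3 the array with cin in Cy5 gave -0.04 for IAA3, against -0.58 to -0.34 on the other arrays of the same design. The class II TCP gene TCP4 stood at 0.15 ± 0.06 (adjusted p = 0.825) and TCP17 at 0.04 ± 0.24 (adjusted p = 0.976). The cytokinin receptor gene AHK4, the D-type cyclin genes CYCD3;1, CYCD3;2 and CYCD3;3 and the type-A response regulator genes did not meet the signal filter on either design. Of these, ARR4 and ARR17 were above background on some Arabidopsis array and ARR6 on some Antirrhinum array.

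**Figure D1:**
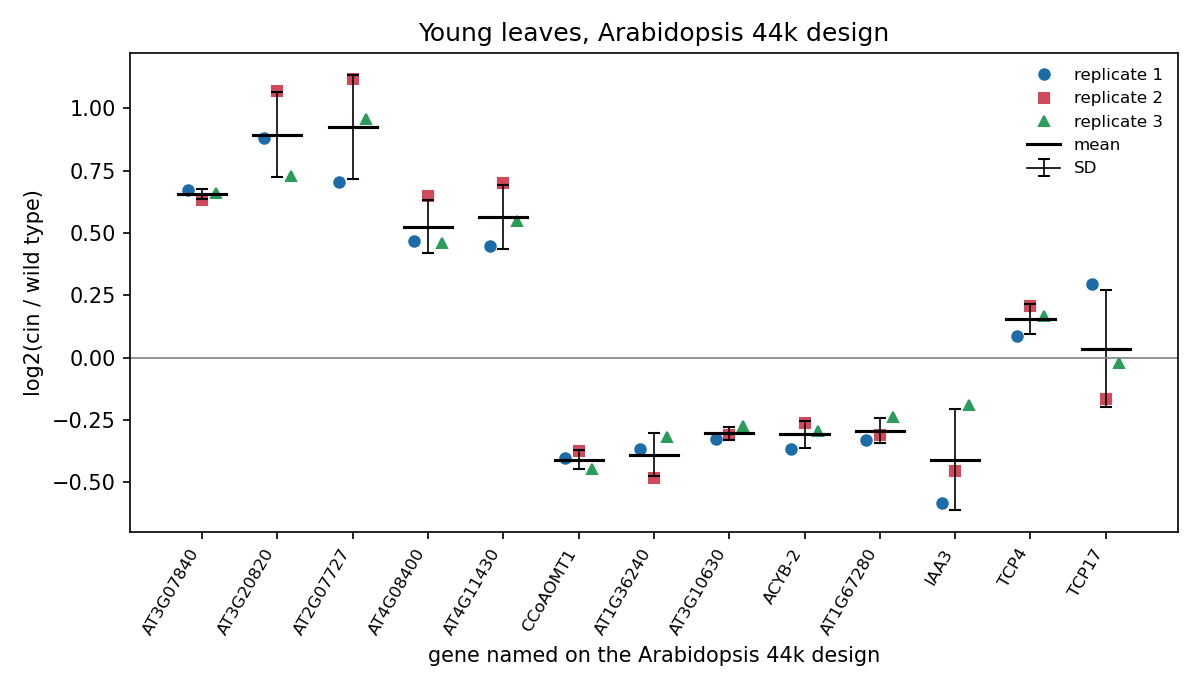
Log2 ratio of cin over wild type (vertical axis) in young leaves on the Arabidopsis 44k design for 13 named genes (horizontal axis), with points for replicates 1 to 3, a bar for the mean and whiskers for the SD. AT3G07840 lies between 0.63 and 0.67 in all 3 replicates, and IAA3 lies below 0 in all 3.

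Of 22 gene lists fixed before the data were examined, 5 had enough measured members on this design and 1 was called by camera with its preset correlation. The cytosolic ribosome list, ribosomal protein genes found by keyword, had 84 measured members with a median of -0.11 (adjusted p = 5.8e-07). That call was lost with an estimated correlation (adjusted p = 0.575 with an estimated correlation), and fry gave an adjusted p of 0.711. The replicates differed in sign, with medians of 0.10, -0.38 and -0.09, and without replicate 2 the mean moved from -0.13 to -0.01 with an adjusted p of 0.539. Members of the photosynthesis list (30, median 0.00), the S-phase histones (6, median -0.02), Aux/IAA (6, median -0.03) and jasmonate (5, median -0.04) gave no call. Without replicate 2 the histone median turned to 0.12 and was called (adjusted p = 0.0058, or 0.872 with an estimated correlation). Aux/IAA was called at -0.22 with Agilent's ratios and at -0.23 with the series matrix values (adjusted p = 0.0361 and 0.0453, or 0.788 and 0.753 with an estimated correlation). The photosynthesis mean was 0.13 without replicate 1, where camera called the list (adjusted p = 5.25e-04) with its preset correlation and not with an estimated one (adjusted p = 0.5678). The cell cycle list had 3 measured members, of which the mitotic kinase gene AUR1 passed when adjusted over the list alone, at -0.17 ± 0.03 (n = 3), and not over all genes (adjusted p = 0.808).

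On the 22k array, a dye-swap partner of replicate 1, light-harvesting and carbon metabolism genes were among the lowest ratios. GAPB, a Calvin cycle dehydrogenase, stood at -2.12, the fructose bisphosphatase gene FBP at -1.89, the chloroplast glutamine synthetase gene GS2 at -1.65 and LHCB1.2 at -1.54. The photosynthesis list had 13 measured members with a median of -0.995, at the 0 percentile of 10000 random lists matched on intensity. With median centring, which moved the median of all loci to 1.065, it stood at 0.94. The same list on the 44k array of replicate 1 had a median of -0.15 over 30 members. Light-harvesting and photosystem genes went both ways there. LHCB1.2 stood at 0.45, LHCA1 at 0.47 and PSAF at 0.04, against -1.54, -1.47 and -1.53 on the 22k array. LHCB3 at -0.40 and LHCA4 at -0.20 were lower on both. Cytosolic ribosome genes had a median of 0.04 over 54 members on the 22k array, at percentile 99. Their median on the 44k array of replicate 1 was 0.10 over 84 members, also above 0, while the 3 replicates together gave the lower call. S-phase histones had a median of 0.16 over 6 members, at percentile 95.6. Among the highest ratios were the ACC oxidase gene AT1G12010 at 0.97, DUT1 at 0.91 and the histone H2A variant gene HTA11 at 0.66. Of 800 features measured in both channels, 30 lay beyond 2-fold and all 30 were lower in cin. There is 1 such array, so these values have no replicate check. The correlations took in 1489 loci, those well above background in at least 1 channel of the 22k array and kept on the 44k design. Over these loci the 22k ratios correlated with the 44k array of replicate 1 at r = 0.08. They correlated with the replicate 2 arrays at -0.32 (cin in Cy3) and -0.10 (cin in Cy5), and with the replicate 3 arrays at 0.00 and -0.01.

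Young cin leaves on the Antirrhinum design gave larger ratios for some of the same loci. AT3G07840 was 1.46 ± 0.02 higher on the log2 scale (SD, n = 2) and AT4G11430 was 1.398 ± 0.131 higher. LRX2, a leucine-rich repeat extensin of the cell wall, stood at 1.07 ± 0.06, AT5G36920 at 1.02 ± 0.04 and the locus AT1G26240 at 0.95 ± 0.00. None of these passed (adjusted p = 0.411 for each).

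HTB11, a histone H2B gene, had the lowest ratio of the named loci at -3.55 ± 0.16 (n = 2, adjusted p = 0.411). It was below the threshold without background subtraction (adjusted p = 0.0383), with median centring (adjusted p = 1.01e-06), with Agilent's own processed ratios (adjusted p = 0.00887) and with the series matrix values (adjusted p = 0.00768). GAPB was at -0.76 ± 0.09 (adjusted p = 0.430), and GSTF9, a glutathione transferase, was at -0.77 ± 0.27 (adjusted p = 0.478). The geranylgeranyl pyrophosphate synthase locus AT3G32040 stood at -0.50 ± 0.03 and AT5G39140 at -0.49 ± 0.02 (both adjusted p = 0.478). TCP17 at -0.05 ± 0.08 and TCP4 at 0.05 ± 0.13 differed in sign between the arrays.

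Over all 15372 features of this design, limma called 0, while 1341 had an unadjusted p under 0.05, 453 higher and 888 lower, against 769 expected by chance. Counts under other scalings reached 112, as given in the closing section. In simulated data with the spread of these 2 arrays and 200 features changed at once, 71% of features changed by 2 and 0% of those changed by 1 on the log2 scale were called. Those shares do not carry over to a few changed features. Most bright features were Antirrhinum transcript assemblies that the files name by identifier alone. Among them gb_PUT-157a-Antirrhinum_majus-13919 stood at 2.29 ± 0.00 and gb_PUT-157a-Antirrhinum_majus-5064 at 1.77 ± 0.07, while gb_PUT-157a-Antirrhinum_majus-11529 stood at -2.38 ± 0.06 and gb_PUT-157a-Antirrhinum_majus-12079 at -1.77 ± 0.05.

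**Figure D2:**
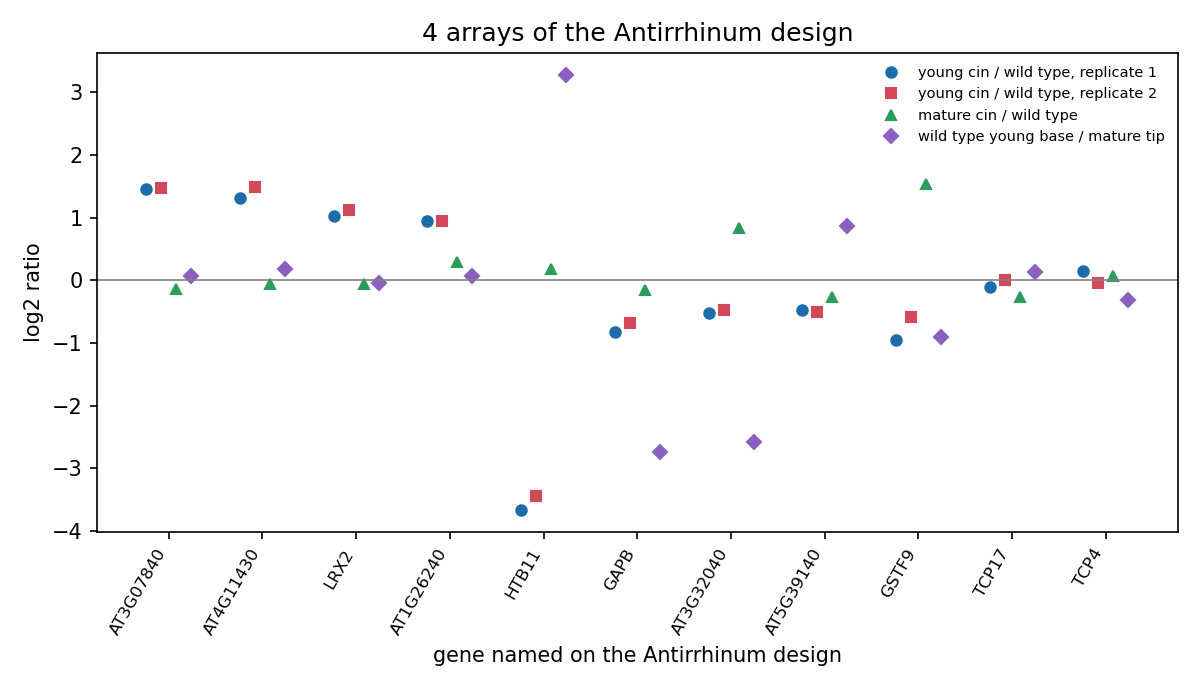
Log2 ratios (vertical axis) of the named young-leaf genes that were above background on the mature array (horizontal axis), on the 4 arrays of the Antirrhinum design; each point is 1 array, and the base over tip value is drawn whether or not it was above background there. HTB11 lies at -3.66 and -3.44 in young cin leaves, at 0.18 in the mature cin leaf and at 3.28 for base over tip.

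Of the 7 lists tested on this design, camera with its preset correlation called 1. S-phase histones, which package newly replicated DNA, are here a list of H3.1 and H4 genes without H2B. Its 13 measured members had a median of 0.12 (adjusted p = 7.3e-06 by camera), 8 of them higher on both arrays and 0 lower on both. That call was lost with an estimated correlation (adjusted p = 0.826 with an estimated correlation), and fry gave an adjusted p of 0.596. The estimated correlation was -0.077, under the preset 0.01, so the loss came without a higher correlation. Camera's unadjusted p rose from 1.0e-06 to 0.121, in a form with little power at 2 replicates. H4f at 0.59 ± 0.13 and H3.1c at 0.52 ± 0.04 had the largest ratios (n = 2, both adjusted p = 0.478). Of the 8, H4b, H4c, H4d, H4e and H4g were dim, with log2 levels of 6.69 to 7.84 in cin against 14.1 for H4f. Their ratios lay between 0.05 and 0.19 on each array. With median centring the list's median turned to -0.19 against -0.10 for all loci, and the call was lost (adjusted p = 0.411). The photosynthesis list (34, median -0.03, adjusted p = 0.0994) was not called. Camera called it lower without background subtraction, with median centring, with Agilent's ratios and with the series matrix values, at medians of -0.09, -0.59, -0.17 and -0.15, and none of these 4 calls held with an estimated correlation (adjusted p = 0.809, 0.929, 0.832 and 0.859). Aux/IAA (5, median -0.01) was called by fry's mixed test alone (adjusted p = 0.0480). Cytosolic ribosome (108, median 0.00), expansins and xyloglucan enzymes (7, median -0.01), jasmonate (5, median 0.00) and vascular tissue (5, median 0.04) gave no call. With median centring the ribosome list was called at a median of -0.56 (adjusted p = 5.0e-20, or 0.929 with an estimated correlation).

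In the mature cin leaf, the light-harvesting genes had low ratios and several histone genes had high ones; there is 1 such array and no test. The antenna genes LHCA2 at -2.11, LHCB3 at -1.84, LHCB1.1 at -1.82, LHCB1.3 at -1.65 and LHCB1.2 at -1.48 were among the 10 lowest loci, with the photosystem I subunit gene PSAF at -2.04. The others were AT3G20820 at -1.62, AT2G12905 at -1.52, the receptor kinase gene AT3G24240 at -1.51 and the chlorophyll-binding protein gene AT5G28450 at -1.34. The EF-hand calcium-binding protein gene AT4G27280 was highest at 5.65, followed by AT1G69900 at 3.02, the plastid glucose 6-phosphate translocator gene GPT2 at 3.01, AT2G32190 at 2.98, AT1G05340 at 2.92 and AT3G22240 at 2.47. The alpha-galactosidase gene AGAL1 at 2.06, the tetraspanin gene TET7 at 1.92, the histone H3 gene H3.1e at 1.78 and MEE23 at 1.63 completed the 10 highest.

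By list, 34 of 39 photosynthesis genes were lower in the mature cin leaf, 12 of them beyond 2-fold, and the median of -0.55 lay at the 0 percentile of the random lists. S-phase histones had a median of 0.41 over 12 members, above all 10000 random lists, with H3.1c at 1.18 and H3.1d at 1.08 next to H3.1e. Cell cycle genes had a median of 0.15 over 6 members, at percentile 99.3, and cytosolic ribosome genes one of -0.07 over 106 members, at percentile 0.1. On the 2 young arrays the ribosome list stood at -0.07 (percentile 0) and at 0.04 (percentile 100), so a percentile of this size turned between replicate arrays. With median centring, which moved the median of all loci to 0.15, photosynthesis stood at -0.26, histones at 0.70, cell cycle at 0.27 and ribosome at 0.21, so the ribosome list turned. Gibberellin (5, median 0.12), jasmonate (8, median 0.02) and expansins and xyloglucan enzymes (10, median -0.01) lay between percentiles 41.5 and 96. Of 15052 features measured in both channels, 978 were higher and 441 lower in cin beyond 2-fold, against 2084 and 134 with median centring and 1292 and 902 with Agilent's ratios.

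Proliferating base was set against mature tip in the wild type on 1 array, again without a test. Of the 10 highest loci, H3.1e stood at 5.76, the cyclin-dependent kinase subunit gene CKS2 at 4.21, and the H2B genes HTB1 at 3.47, HTB4 at 3.37 and HTB11 at 3.28. The thaumatin-like gene ATLP-1 at 3.28, the H2B locus AT3G09480 at 2.98, the germin-like gene GER3 at 2.94, the lipase gene AT4G28780 at 2.87 and the H3 locus AT1G75600 at 2.73 followed. Lowest were PPDK at -4.26, the plastid isoprenoid gene DXR at -4.24, the photorespiratory HPR at -3.75, the ferric reductase gene FRO7 at -3.73 and AT1G52870 at -3.65. PEX11E, of peroxisome division, was at -3.08, ALP at -2.92, GAPB at -2.74, AT3G32040 at -2.58 and RSR4 at -2.54.

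Translation genes were higher in the base: 63 of 65 cytosolic ribosome genes lay above 0 with a median of 1.61, above all 10000 random lists. Photosynthesis genes had a median of -0.86 over 19 members, at the 0 percentile. S-phase histones had a median of 0.55 over 5 members, at percentile 64.7, and the 5 ranged from -0.37 for H3.1c to 5.76 for H3.1e. That list holds H3.1 and H4 genes and leaves out the H2B genes named above. Median centring moved the median of all loci to 0.79, and photosynthesis then stood at 0.95, histones at 1.72 and ribosome at 3.05, so the sign of the photosynthesis list depended on that choice. Of 11161 features, 2230 were higher and 1948 lower in the base beyond 2-fold. Median centring gave 6552 higher and 538 lower, and Agilent's ratios 2665 higher and 2695 lower, where the majority turned.

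**Figure D3:**
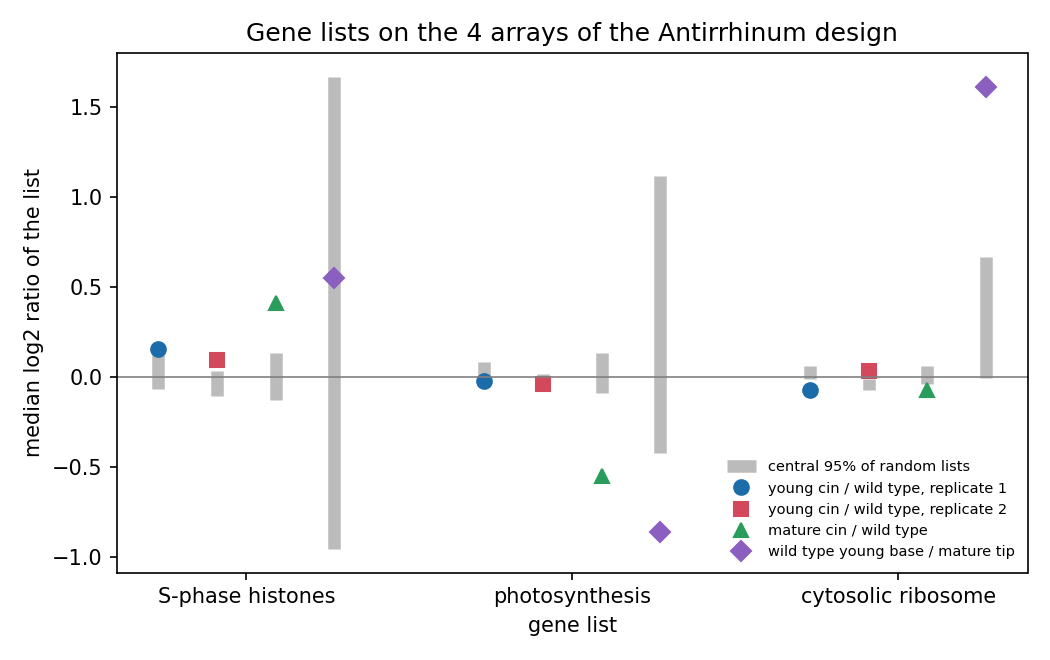
Median log2 ratio (vertical axis) of 3 gene lists (horizontal axis) on the 4 arrays of the Antirrhinum design, 1 point per array, with grey bars for the central 95% of 10000 random lists of the same size matched on intensity. The mature cin array lies at 0.41 for S-phase histones and at -0.55 for photosynthesis, and base over tip lies at 1.61 for cytosolic ribosome.

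Ratios of the same loci were then compared between designs and tissues, with correlations across genes, which are not independent replicates. Young cin ratios on the Arabidopsis and Antirrhinum designs correlated at Pearson r = 0.24 and Spearman rho = 0.15 over 1525 loci. That r fell to 0.0151 with median centring and to between 0.0655 and 0.191 without 1 replicate. The 50 highest loci of each design had 19 in common against 1.64 expected, a count chosen after the values were seen. These included AT3G07840, AT4G11430, AT4G08400, AT3G20820 and AT5G36920, and 6 of the 19 were extensin-type by words in their annotation. That mark left out LRX1, which was also among the 19 and shares its family name with the extensin LRX2. Whether the 2 designs carried the same probe sequences for these loci was not examined, and the Antirrhinum design held 1490 catalogue probes for Arabidopsis loci. Neither the overlap nor the r of 0.24 therefore shows agreement of independent probes. Young and mature cin ratios correlated at r = 0.11 and rho = 0.17 over 14353 features. Young cin and base over tip gave r = 0.22 and rho = 0.05 over 13114 features. In both of these, features needed to be well above background in only 1 channel of the single array. The last 2 correlations turned negative with median centring, at r = -0.05 and r = -0.12. The 2 young Antirrhinum arrays correlated with each other at r = 0.32 and rho = 0.10, with 50.7% of features of the same sign. On the Arabidopsis design the means of replicates 2 and 3 correlated at r = 0.40, of 1 and 2 at -0.06 and of 1 and 3 at 0.03.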

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

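Of the tests given in this part, the brightest-gene correlation for replicate 1 and the counts over sign patterns were set before their results were seen. The other tests of repeated sequence, leaf state, dye and slide were chosen after the result was seen.

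On the Arabidopsis 44k design the replicate 1 array had 13.3% of probes above background in either channel, farther from the other 5 young Arabidopsis arrays (7.81 to 9.66%) than a sample of their spread would lie at the 95% level. AT3G20820 had a ratio of 1.39 on the replicate 2 array with cin in Cy3, against 0.73 to 0.88 on the other 4 arrays of the 44k design. These were 2 of 21 such checks, of which chance alone gives about 1 in 20.

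The ratios of replicate 1, a single array with cin in Cy3, agreed little with the others: its correlation across genes with the mean of replicates 2 and 3 was -0.0381, while replicates 2 and 3 correlated at 0.397. By dye, its Spearman rho was -0.21 and -0.14 with the arrays of replicates 2 and 3 that had cin in Cy5, and 0.01 and 0.07 with those that had cin in Cy3. With the young Antirrhinum arrays it correlated at r = 0.16, against 0.10 for replicate 2 and 0.25 for replicate 3. Exchanged dye labels would turn the sign of shared effects, and a clearly negative correlation with the dye-balanced mean was not seen. Such a correlation would follow only from a strong cin effect shared by all replicates. The 0.397 of replicates 2 and 3 may come from their shared slide, so exchanged labels stay open. Dye bias of that unswapped array was not tested and stays open. Low signal on that array would leave a positive correlation among bright genes, and in the brightest 626 genes it was -0.0917, against 0.44 for replicates 2 and 3. The slide cannot be told apart from the replicate, because the 0.397 comes from replicates that share a slide and replicate 1 is alone on its own. No biological explanation was tested.

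Young and mature cin leaves gave ratios of opposite sign for 9 of 31 named genes and 1 of 7 lists measured on both, with both young arrays on 1 side and the single mature array on the other; these differences were not tested. Of the 31 genes 17 had 1 sign on both young arrays, so unrelated signs would give 8.5, close to the 9 found. HTB11 went from -3.66 and -3.44 in young leaves to 0.18 in the mature leaf, where its log2 levels were 6.49 in cin and 6.31 in wild type against 8.04 and 11.59 in young leaves. AT3G20820 went from 0.51 and 0.19 to -1.62, PSAF from 0.25 and 0.06 to -2.04, and LRX2 from 1.03 and 1.11 to -0.0572. AT3G07840 went from 1.45 and 1.47 to -0.14 and AT4G11430 from 1.306 and 1.49 to -0.0562. GSTF9 went from -0.96 and -0.58 to 1.54, AT3G32040 from -0.52 and -0.48 to 0.84, and MEE23 from -0.10 and -0.08 to 1.63. The Aux/IAA list went from medians of -0.03 and -0.07 to 0.19 over 4 members.

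In the mature cin leaf the photosynthesis list was low (median -0.55, 39 members) and S-phase histones were high (median 0.41, 12 members) on an array without a dye swap. The median dye term of those members, from the young dye-swapped pair, was -0.0490 for photosynthesis and -0.00827 for histones, small beside these ratios. Across members its SD was 0.25 and 0.18. The 2 young arrays are also different replicates, so dye and replicate cannot be told apart in that term. Dye bias on the mature array therefore stays open. A younger leaf state in cin stays open, because the values point both ways. Base over tip had a median of 0.53 over the same 12 histone members, or 2.32 with Agilent's ratios. Of these members, 5 were above background in both channels there. Their median was 0.55, or 0.50 with Agilent's ratios. The 0.55 lay at percentile 64.7 of the random lists, so these H3.1 and H4 genes were not set apart. H2B genes, which the list leaves out, were among the highest loci there. For photosynthesis the base over tip median was -0.86 over the 19 genes measured in both channels there. It kept its sign without background subtraction (-0.85) and with Agilent's ratios (-0.68), and turned to 0.95 with median centring (all loci 0.79). Over the 39 members, which include genes not above background in both channels there, it was -0.02. That value turned to 0.42 with Agilent's ratios, against -0.89 in mature cin. Mature cin and base over tip correlated at only 0.0699 across features. The ribosome list stood at -0.07 in mature cin, or 0.21 with median centring (all loci 0.15), against 0.97 in the base over the same 106 members; with Agilent's ratios these were -0.15 and 1.76. A change in the photosynthesis and histone genes themselves stays open, as does any difference between the 2 mature RNA samples, since there is 1 array.

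The loci among the 50 highest on both designs in young cin leaves may share repeated probe sequence, because 6 of these 19 were annotated as extensin-type. A 12-base word common to extensin-type probes of at least 3 other loci was found in 26.3% of the 19, against 0.656% of all 1525 loci, so repeated sequence remains possible for those and leaves most of the 19 without such a word. Loci not annotated as extensin-type that carried the word numbered 2, AT1G26240 at 0.95 and AT5G28610 at 0.90. Their median young ratio was 0.92 against 0.00 for the rest. The annotation can miss members of the family, as it did LRX1, so these 2 are not a sure contrast. A younger leaf state was not excluded for these loci. Their median base over tip ratio was 0.0762 against a median young cin ratio of 0.91 on the Antirrhinum design, but 0.84 against 1.95 with Agilent's ratios. A true difference in a wall protein family stays open as well.

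With 3 replicates there are 4 sign patterns of the replicate means, too few for a share under 0.05. In the real pattern limma called 0 genes and camera 1 list; as many genes were called in 4 of 4 patterns and as many lists in 4 of 4, and the highest of the other patterns gave 0 genes and 2 lists.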

How the results depend on the processing

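Of the alternatives given in this part, 3 were chosen after the data were seen: leaving out loci that share repeated sequence, which moved the correlation between designs from 0.24 to 0.22, using the 4 arrays of the shared slide, which called 0 genes, and the settings of the 22k array. The causes of the changes below were not tested unless stated.

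On the Arabidopsis design 0 genes passed under most settings. The count was 1 (lower) with Agilent's processed log ratio, 1 (lower) with the series matrix values and 1 without a filter on dim probes, the last being AT3G07840 (adjusted p = 0.0205). Lists called went from 1 to 2 with Agilent's ratios and with the series matrix values, both adding Aux/IAA (adjusted p = 0.0361 and 0.0453). Without each replicate they ranged from 1 to 2 and were not the same lists: camera called photosynthesis higher without replicate 1, and without replicate 2 it lost the ribosome and called S-phase histones higher. Arrays as units with a dye term and the replicate number as a block gave 0 genes and 1 list, and the slide as a random block gave the same counts, so neither ended a call. The mean over the probes of a locus and the 22k array joined to replicate 1 each gave 0 genes and the ribosome list. No list call under any setting on either design held with an estimated correlation where one was fitted. That form of camera has little power with so few replicates, so these losses neither uphold nor refute the calls. The groups lie on different designs and were not fitted together; between designs the deviations of same-numbered replicates correlated at -0.17 and -0.22 over 1525 loci, and the numbers were not taken as pairs.

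On the Antirrhinum design, where 0 features passed as reported, 4 passed without background subtraction (1 higher, 3 lower), 44 with median centring (1 higher, 43 lower), 107 with Agilent's ratios (60 higher, 47 lower) and 112 with the series matrix values (62 higher, 50 lower). Each of these 4 settings called 2 lists in place of 1: S-phase histones higher and photosynthesis lower, except with median centring, where photosynthesis and the ribosome were lower and the histone call was lost. Median centring moved the median of all features to -0.49 there and that of the Arabidopsis design to 0.03. Without replicate 1 or 2 no test remained.

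Beyond 2-fold in the mature cin leaf lay 1419 features, 68.9% of them higher; with median centring 2218 did (94.0% higher) and with Agilent's ratios 2194 (58.9% higher). For base over tip 4178 became 7090 with median centring, where the share higher went from 53.4 to 92.4%. All 20 named genes of the mature and of the base over tip array kept their sign without background subtraction, with median centring and with Agilent's ratios. On the 22k array all 20 did without background subtraction and with Agilent's ratios, and 13 with median centring.

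The correlation between designs of 0.24 was 0.0151 with median centring, 0.32 with Agilent's ratios, 0.11 without a filter and 0.0655 to 0.191 without each replicate. With median centring, young with mature cin reversed from 0.11 to -0.0478 and young cin with base over tip from 0.22 to -0.12. Without each young array these were 0.0698 to 0.111 and 0.0812 to 0.268. Across other settings, 232 tested values of single named genes kept sign and call, 13 newly passed, and 8, all of TCP17 or TCP4, changed sign without a call. For the tested lists 75 values kept camera's direction and call, 20 changed direction without a call, 9 were newly called, 1 of them with its direction changed (S-phase histones without replicate 2), and 2 lost the call.

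Signal over background limits what the Arabidopsis design can show, with at most 13.3% of probes above it.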

Other observations

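The H2B genes described here and their values were chosen after the values were seen. On the Antirrhinum design HTB11 had a young cin ratio of -3.55 ± 0.16 (SD, n = 2), while the 3 other measured genes with an HTB symbol lay above 0: HTB1 stood at 0.40 ± 0.10, HTB4 at 0.44 ± 0.33 and HTB9 at 0.27 ± 0.00 (adjusted p = 0.522, 0.615 and 0.565 with limma). Base over tip was high for all 4, at 3.28 for HTB11, 3.47 for HTB1, 3.37 for HTB4 and 2.07 for HTB9. In the mature cin leaf HTB1 was at 0.65, HTB4 at 0.66 and HTB9 at 0.21. On the Arabidopsis design the probe named HTB4 had a low ratio, at -2.15, -0.82 and -0.47 in the 3 replicates (mean -1.15 ± 0.89, adjusted p = 0.825 with limma). HTB1 stood at -0.23 ± 0.37 there. Which H2B gene of Antirrhinum each of these probes read was not tested, so the 2 designs cannot be set against each other gene by gene.

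AT4G27280, the EF-hand gene that was highest in the mature cin leaf at 5.65, stood at 0.58 and 0.57 on the young Antirrhinum arrays (mean 0.58 ± 0.00, n = 2, adjusted p = 0.455 with limma). GPT2, at 3.01 in the mature leaf, stood at 0.13 and -0.12 in young leaves.

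Annotated extensin-type loci were also chosen after the values were seen. Their median was 0.03 over 57 loci on the Antirrhinum design against 0.01 for the other loci, with 22 higher and 10 lower on both arrays. Camera with its preset correlation gave p = 3.5e-06 for them there, and the call was lost with an estimated correlation (p = 0.306). The median was 0.00 over 39 loci on the Arabidopsis design, with 8 higher and 6 lower in all 3 replicates.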
